A study of Mus musculus with 5 samples.

How the data were processed

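RNA from livers of CCl4-injected mice (2 arrays) and vehicle-injected mice (3 arrays) was labelled with Cy3 and hybridised to an Agilent array with 151113 probes for mouse messenger RNAs and long non-coding RNAs. The design text mentions more CCl4 samples than are listed, and a further one was not used here. The log2 intensities were deposited by the authors after quantile normalization between arrays, since values of equal rank differed by at most 0.0012 between arrays. The base of the logarithm was inferred from the range, 1.82 to 18.71. The scanner output came from Agilent Feature Extraction 10.7, and the background handling and the normalization tool are not given in the sources used here. The detection flags P, M and A per probe and array, a unit other than intensity, are per the file headers as deposited; the rule behind them is not given either. Scanner files were not used here, so slides and background were not examined. The flag columns headed WT were read as the vehicle group.

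Control probes (68) and probes for other species (127) were left out, and 5 further per-array columns of the annotation were not used. Of the 150918 probes kept, 111488 belonged to the lncRNA class and 39430 to the mRNA class. Among mRNA-class probes with a symbol (33207), the name was taken from a RefSeq gene table on GRCm38.p6 by accession for 27428, by symbol for 3477 and by synonym for 501, and from the file for 1801. Another 6223 had no symbol. The probes fell into 20145 protein-coding genes, 38338 non-coding transcripts and 8052 others. Each was represented by its brightest probe over all 5 arrays, chosen without regard to group. Probes with a mean under the median of all probe means, a log2 intensity of 5.08, were left out, which left 46599 genes and transcripts.

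Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, contrast CCl4 minus vehicle, eBayes with trend, two-sided), with Benjamini-Hochberg adjustment over all 46599 and a threshold of 0.05. Where the probe standing for a gene was flagged P on no array of a group, its fold is given as a lower bound. For that bound each array of the lower group took the higher of the gene's value and the array's lowest signal among probes flagged P throughout the group, which was 3.98 and 3.83 on the CCl4 arrays and 4.43, 4.15 and 4.54 on the vehicle arrays. Before the data were examined, 38 gene lists were fixed from general knowledge, and 67 of their 978 measured members stood on more than 1 list. Lists were tested with limma's camera (preset correlation 0.01), with camera and an estimated correlation, and with fry, each adjusted over the lists.

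The named genes were set by a rule fixed before the data were examined. It took the 10 protein-coding genes with the largest rise and the 10 with the largest fall among those past the threshold without overlap of the groups. It also took the 5 non-coding transcripts with the largest rise and the 5 with the largest fall by the same criterion, and up to 2 members with the largest rise and 2 with the largest fall past the threshold from each list. Col1a1, Col1a2, Col3a1, Acta2, Timp1, Tgfb1, Ccn2, Pdgfrb, Cyp2e1, Cyp7a1, Alb, Hnf4a, Mki67, H19, Meg3, Gas5 and Malat1 were included whatever their result. The rule named 155 genes and transcripts. Replicate numbers are not said to pair animals, so no block was used in the test reported, and a block was tried as an alternative.

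The test was tested on simulated data with the noise of these arrays and 46599 genes. With 200 changed genes in each of 5 runs, 0% of changes of 0.5 log2, 9% of those of 1 and 55.2% of those of 2 were recovered, and 2 of 214 calls were false. With 10000 changed genes in a run, 42.2%, 80.6% and 95.6% were recovered and 4.1% of calls were false. Of 38 simulated lists, 1 was called, and it was the shifted one. The simulated noise was independent between genes, whereas the correlation estimated within the fixed lists reached 0.66, for cholesterol synthesis. The simulation therefore cannot show how often camera with the preset correlation calls such lists falsely.

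Alternatives fixed before the data were examined were other brightness filters, quantile normalization repeated, median centring, cyclic loess, the mean of a gene's probes, limma without trend or with robust spread, array weights, stricter calls, the replicate number as a block, each array left out, and the other list tests. Chosen after seeing the data were scaling by 10 spike-in probes, separate normalization of mRNA-class and lncRNA-class probes, a filter on detection flags and a protein-coding background for the lists. Non-coding transcripts were located by the coordinates in the annotation, which were read as GRCm38 because 366 of 373 clones with a RIKEN locus overlapped it there. Agilent lincRNA coordinates were not used. Overlap with protein-coding genes was permuted over genes 10000 times. Tables and figures were made with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.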

Results

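Total liver RNA of male C57BL6/J mice was measured on single-colour Agilent arrays with probes for messenger RNAs and long non-coding RNAs. The arrays analysed here numbered 5. Of these, 2 came from livers of mice injected into the abdomen with carbon tetrachloride (CCl4), a solvent that hepatocytes turn into a toxic radical, and 3 from mice injected with vehicle. Injections were given 2 times per week for 8 weeks. Values are log2 intensities. Every array had a median of 5.135 over all probes, because the values were already equalised between arrays. Probes with a detection flag of P made up 61.6% and 63.1% of non-control probes on the CCl4 arrays, against 56.6%, 58.8% and 55.4% on the vehicle arrays. Pearson's r over all genes and transcripts tested was 0.983 between the CCl4 arrays, 0.989 to 0.992 among the vehicle arrays and 0.924 to 0.943 between the groups. The first principal component held 80.4% of the variance and separated the groups, and the second, with 9.4%, placed the CCl4 arrays at its extremes. The labels do not state that each array holds a different animal, so the p-values below measure spread between these arrays, whose small number limits the precision.

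Which protein-coding genes differ between CCl4 and vehicle livers was the first question. Livers after CCl4 had far more transcript of Gpnmb, a glycoprotein of lipid-laden macrophages, of Timp1, an inhibitor of matrix-degrading proteases, and of the fibrillar collagens. They had far less of Cyp8b1 and Cyp7a1, enzymes of bile acid synthesis, and of Hsd3b5, a male-specific steroid enzyme of liver. Timp1 rose from a log2 intensity of 5.83 ± 0.87 (SD, n = 3) to 13.91 ± 0.51 (SD, n = 2), which is 270-fold. Col1a1, a chain of type I collagen, rose 54.3-fold, from 8.52 ± 0.38 (SD, n = 3) to 14.28 ± 0.23 (SD, n = 2). Hsd3b5 was 359-fold lower, at 6.42 ± 1.60 (SD, n = 2) against 14.91 ± 0.43 (SD, n = 3), and over the alternatives its log2 change ranged from -9.62 to -7.36.

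Of 14937 protein-coding genes tested, 6964 (46.6%) passed an adjusted p of 0.05, 4300 higher and 2664 lower after CCl4. Changes of at least 2-fold among these numbered 2224 higher and 983 lower. Both CCl4 arrays lay above all vehicle arrays or both below them in 70.3% of the genes, where chance gives 20%. Among the 10 genes with the largest fitted rise were Gpnmb, at least 214-fold higher, and the neutrophil granule genes Ltf, at least 107-fold, Ngp, at least 72.3-fold, and Mpo, with a log2 change of 7.04. These folds are lower bounds because no vehicle array detected Gpnmb, Ltf or Ngp, and leaving out 1 array moved the bounds of Ltf and Ngp to between 53.1- and 215-fold and between 34.9- and 150-fold. The other genes of this set were Timp1, Ly6d (log2 change 7.15), Bhlha15, a transcription factor of secretory cells (6.88), Gldn, at least 47.9-fold, Ctsj, at least 61.7-fold, and Inava, at least 33.5-fold. Among the 10 genes with the largest fitted fall, no CCl4 array detected Cyp8b1, at least 103-fold lower, Clec2h, at least 112-fold, Cpsf4l, at least 44.7-fold, or Fitm1, at least 27.1-fold. The others were Hsd3b5 (log2 change -8.49), the glutamate transporter Slc1a2 (-6.95), the fatty acid elongase Elovl3 (-6.86), the uridine phosphorylase Upp2 (-6.51), Susd4 (-6.45) and the sulfotransferase Sult2a8 (-6.24). The true rank of a gene that 1 group did not detect is not known, and Chil3 (6.77) and Slco1a1 (-6.07), detected on all arrays, were outside these sets although their folds exceed some of the bounds. Elovl3 differed between the CCl4 arrays, with an SD of 2.75 (n = 2). Detection was partial for Mpo, Pdpn, Cyp3a44 and Fgf21 (2 of 3 vehicle arrays), for Col5a2, Wt1, Pnpla3, Acot2 and Egr2 (1 of 3 vehicle arrays) and for Elovl3 (1 of 2 CCl4 arrays), so the sizes of these changes are uncertain. Bright probes of the same gene differed by more than 1 log2 for Slc1a2 (-6.95 to -5.52), Cyp2c38 (-5.04 to -3.08), Cyp2c37 (-4.53 to -3.47), Bhmt (-4.52 to -1.28), Mlxipl (-1.93 to -0.37), Snhg18 (1.47 to 2.80), H19 (-1.07 to 0.37), Noct (-1.04 to 1.10), Malat1 (-0.14 to 1.97) and uc011zab.2 (5.37 to 6.43), besides those given below. Leaving out 1 array moved the fold by more than 1.5 times for Hsd3b5, Elovl3 (-8.81 to -4.91), Mpo (6.12 to 7.96), Chil3 (5.80 to 7.74), G6pc (-3.69 to -1.87), Slco1a1 (-6.80 to -5.33), Car3 (-5.41 to -4.03), Cyp2c37 (-5.12 to -3.95), Cyp3a44 (2.65 to 4.32), Mki67 (3.51 to 4.75), Lcn2 (5.60 to 6.93), Slpi (5.14 to 6.55), Thbs1 (5.12 to 6.32), Pdpn (4.39 to 5.65), Wt1 (5.31 to 6.29), Snhg11 (-4.66 to -3.34) and Ccn2 (0.34 to 1.83), and the bound of Cidea ranged from 11.2- to 27.8-fold. The same held for Cidec (0.77 to 2.45), Acot2 (1.66 to 2.87) and the fitted change of the clone ri|9630038B04 (-6.45 to -5.08).

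Some genes were to be reported whatever their result. Col1a2 and Col3a1 rose by 4.27 and 4.67 log2 (adjusted p = 0.000123 and 0.000105), Acta2, the smooth muscle actin of myofibroblasts, by 3.93 (0.000159), and the receptor Pdgfrb by 3.10 (0.000133). The proliferation marker Mki67 rose by 4.13 (adjusted p = 0.000722) and Tgfb1 by 1.08 (0.00303). Cyp2e1, the main enzyme that activates CCl4, fell by 3.62 log2 (adjusted p = 9.94e-05) from a vehicle mean of 17.90, near the top of the intensity range, and its other bright probe gave -4.72. Cyp7a1 fell by 5.29 (adjusted p = 0.000398). Hnf4a, a transcription factor of hepatocytes, fell by 0.67 log2 (adjusted p = 0.00786), but with the arrays scaled by spike-in probes the change was -0.43 (adjusted p = 0.076) and with the replicate number as a block it was -0.66 (adjusted p = 0.056). Alb had a log2 change of -0.14 (adjusted p = 0.289) near the top of the intensity range. Ccn2 had 1.09 (adjusted p = 0.0833), which became 1.83 (adjusted p = 0.0019) without CCl4 replicate 2 and 1.32 (adjusted p = 0.032) with spike-in scaling.

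The split into higher and lower genes moved with the scaling of the arrays. Spike-in scaling, chosen after the data were seen, raised the median change of all genes from -0.054 to 0.18 log2 and gave 5199 protein-coding genes higher and 1298 lower, so directions are relative to the array-wide scale. With mRNA-class and lncRNA-class probes normalized separately, also chosen after, the numbers were 3509 and 3690, but this centres each class on itself and so evens its split by construction. Without vehicle replicate 1 the lower genes numbered 1740.

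**Figure D1:**
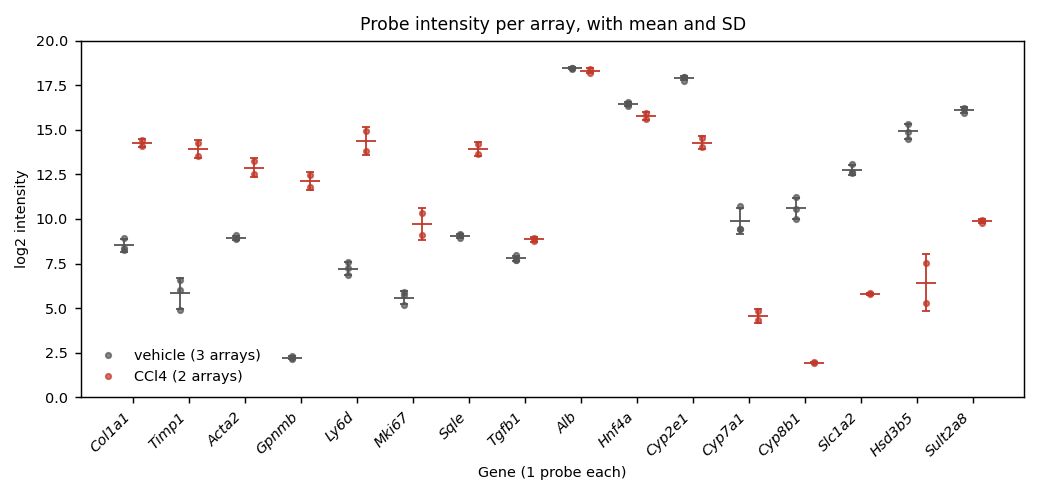
Probe intensity on a log2 scale (vertical axis) for 16 of the named genes (horizontal axis), with each array as a point and the mean and SD of each group as a bar with whiskers; vehicle arrays are grey (n = 3) and CCl4 arrays red (n = 2). Timp1 means stood at 5.83 and 13.91 and Cyp8b1 means at 10.59 and 1.94 in vehicle and CCl4 livers, while the groups met at Alb, with 18.46 and 18.33.

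Gene lists fixed before the data were examined grouped these changes by process and cell type. Genes of scar matrix, myofibroblasts, recruited macrophages, neutrophils, cholesterol synthesis, cell division and stress responses rose. Genes of cytochrome P450s, bile acid and amino acid metabolism, both hepatocyte zones and the male liver pattern fell. Of 38 lists, 19 were higher and 10 lower against the other genes by camera, a competitive set test, with a preset correlation of 0.01 between genes. With a correlation estimated from these arrays no list passed. For each list called with the preset correlation, the adjusted p from that other test therefore stands beside the count. Members named below to complete a small count, without a value, were chosen after their values were seen. The arrays number 5, and the lowest of those adjusted p values was 0.16, for endoplasmic reticulum (ER) stress. At an unadjusted p of 0.05 that test gave 8 lists, while fry, which asks whether a list moves on balance one way, gave 20 higher and 12 lower.

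**Figure D2:**
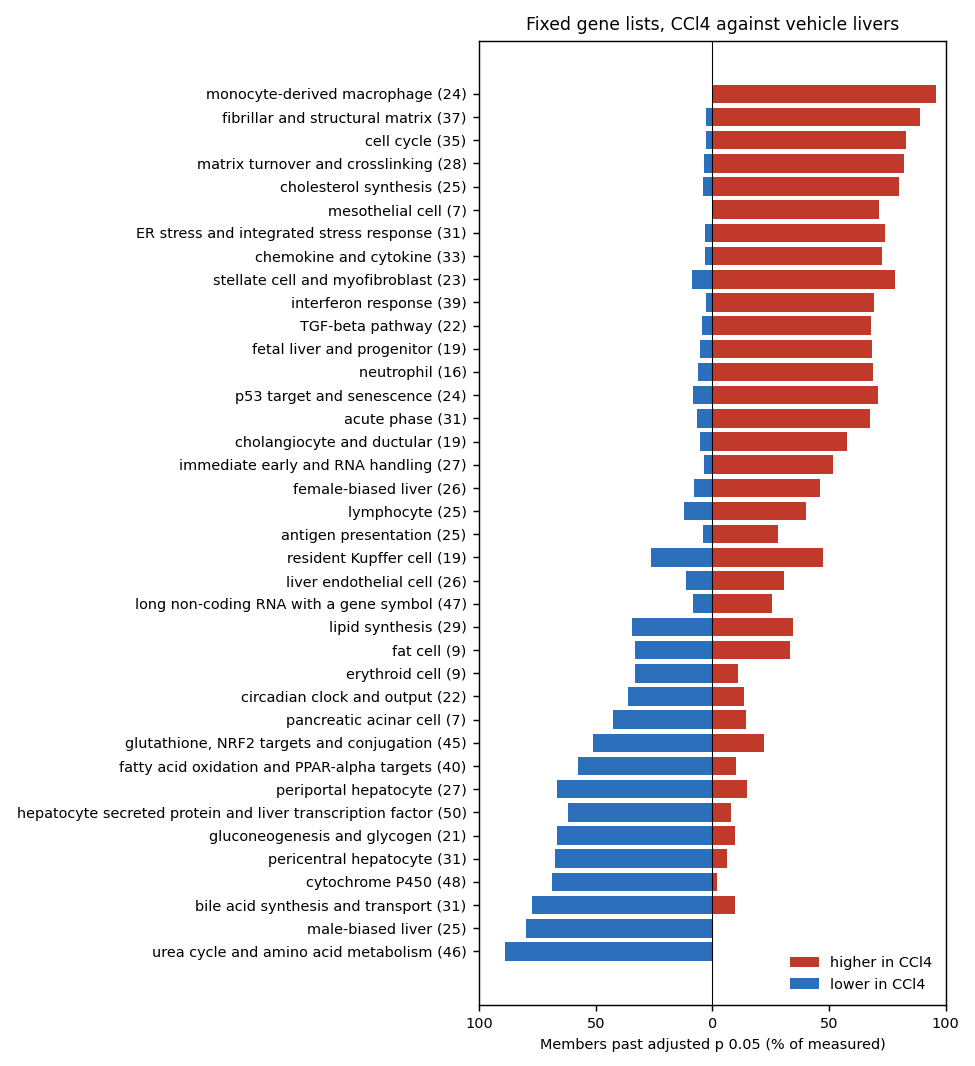
Share of each list's measured members (in %, horizontal axis) that were higher (red, right) or lower (blue, left) in CCl4 than in vehicle livers past an adjusted p of 0.05; measured members stand in parentheses. The monocyte-derived macrophage list had 23 of 24 members higher, and the urea cycle and amino acid list 41 of 46 lower.

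Matrix genes rose together with the genes of the cells that make matrix. Of 37 measured fibrillar and structural matrix genes, 33 rose and 1 fell, with a median of 2.41 log2 (adjusted p = 1.2e-18; adjusted p = 0.19 with an estimated correlation). Col1a1 (5.76) and Col5a2 (4.88) rose most. Vcan, a proteoglycan, was the member lower by its brightest probe (-0.42, adjusted p = 0.0237), yet the mean of its probes gave 2.77 (adjusted p = 9.1e-05), and with spike-in scaling it was -0.18 (adjusted p = 0.46). Matrix turnover and crosslinking genes rose in 23 of 28 cases and fell in 1, median 2.94 (adjusted p = 1.7e-12; adjusted p = 0.19 with an estimated correlation). Timp1 led them, followed by the metalloprotease Adam8 at 5.82, while the lysyl hydroxylase Plod1 had -0.70, which spike-in scaling made -0.46 (adjusted p = 0.084) and the mean of its probes -0.26 (adjusted p = 0.18), its other bright probe being at -0.08. Stellate cell and myofibroblast genes rose in 18 of 23 cases and fell in 2, median 1.48 (adjusted p = 5.7e-09; adjusted p = 0.19 with an estimated correlation). Pdpn (5.08) and S100a6 (4.59) rose most, and Ecm1 (-0.87) and Colec11 (-0.62) were lower; with spike-in scaling Colec11 had -0.38 (adjusted p = 0.19). Genes of the TGF-beta pathway rose in 15 of 22 cases and fell in 1, median 0.93 (adjusted p = 3.1e-06; adjusted p = 0.23 with an estimated correlation). The matricellular activator Thbs1 rose by 5.72 and the ligand Tgfb3 by 3.11, and the oxidase Nox4 was 2.83-fold lower. Adjusted over the list alone, the counts of these lists were the same, except that 17 TGF-beta pathway genes were higher.

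Markers of recruited macrophages and neutrophils rose, while the lists of resident macrophages and lymphocytes were not called. Of 24 monocyte-derived macrophage genes, 23 rose and none fell, median 3.11 (adjusted p = 1.2e-17; adjusted p = 0.22 with an estimated correlation). Chil3, a lectin of activated macrophages, rose by 6.77 behind Gpnmb. Neutrophil genes rose in 11 of 16 cases, median 4.61 (adjusted p = 3.1e-06; adjusted p = 0.26 with an estimated correlation). Those were led by the granule genes Ltf and Mpo, while the surface marker Ly6g had -0.56 (adjusted p = 0.0489), a fall lost with spike-in scaling (-0.32, adjusted p = 0.32) and without CCl4 replicate 2 (-0.31, adjusted p = 0.18). Chemokine and cytokine genes rose in 24 of 33 cases, median 1.57 (adjusted p = 2.8e-09; adjusted p = 0.26 with an estimated correlation). The neutrophil attractant Cxcl5 was at least 28.1-fold higher and Cxcl14 rose by 6.25, while the interferon-induced Cxcl9 had -1.22, with an adjusted p of 0.0283, or 0.09 without CCl4 replicate 1. Kupffer cell genes went both ways, 9 higher and 5 lower of 19, and the list was not called (adjusted p = 0.11; 0.024 without vehicle replicate 2). With spike-in scaling 10 were higher and only C6 was lower past the threshold, though Cd163 still had -0.53 in place of -0.76. The scavenger receptor Marco rose by 4.08 and Adgre1 by 1.63, and C6 fell by 1.74, with Cd163, Clec4f, Fcna and Nr1h3 also lower. The lymphocyte list had 10 higher and 3 lower of 25 (adjusted p = 0.075), and passed without CCl4 replicate 2 (adjusted p = 0.025) or without vehicle replicate 2 (0.034). Its antibody-joining chain Jchain rose by 5.81 and the B cell gene Ms4a1 by 2.02, while the T cell gene Cd6 fell by 2.02 (its other bright probe gave 0.05), with Zap70 and Cd4 also lower; with the classes normalized separately 7 were higher and 4 lower. Single alternatives ended the calls of Cd163 in 9 of 18 and of Zap70 in 3 of 19 cases, with adjusted p up to 0.17 and 0.093. Antigen presentation genes rose in 7 of 25 cases and fell in 1 (median 0.69, adjusted p = 0.0094; adjusted p = 0.43 with an estimated correlation). That share of risers was near the one among all protein-coding genes, 4300 of 14937. With spike-in scaling 12 antigen presentation genes were higher and 0 lower, and with the classes normalized separately 5 and 1. The call held in 16 of 22 alternatives (adjusted p from 0.00015) and was lost without CCl4 replicate 1 (0.052), with the classes normalized separately (0.055), by fry (0.072), with a filter at the 75th percentile (0.073), with a protein-coding background (0.14) and with an estimated correlation. Batf3 (1.47) and H2-DMb1 (1.43) rose most, and the fall of H2-K1 (-0.31) shrank to -0.08 (adjusted p = 0.72) with spike-in scaling. Counts adjusted over the list alone gave the Kupffer list 10 higher and the chemokine list 2 lower, with the other counts of these lists unchanged.

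Other cell types differed from one another. Cholangiocyte and ductular genes rose in 11 of 19 cases and fell in 1, median 1.85 (adjusted p = 7e-06; adjusted p = 0.28 with an estimated correlation). The stem cell marker Prom1 (4.85) and osteopontin, Spp1 (4.51), rose most, and the tight junction gene Cldn7 fell by 3.60, with its other bright probe at 1.25. Mesothelial genes rose in 5 of 7 cases, median 3.13 (adjusted p = 0.00058; adjusted p = 0.26 with an estimated correlation), namely Slpi (5.86), Wt1 (5.66), Msln, Gpm6a and Muc16. Liver endothelial genes went both ways, 8 higher and 3 lower of 26 (adjusted p = 0.2, or 0.012 by fry), with a median of 0.07. Risers were about as frequent as among all protein-coding genes (4300 of 14937), and 15 members were not called. Spike-in scaling gave 10 higher and 1 lower, and separate normalization of the classes 4 and 4 with a median of -0.06. Cd34 rose by 2.44 and Vwf by 1.51, both genes of capillary and large-vessel endothelium, and Ehd3 of the sinusoids fell by 0.92, with Kdr and Clec4g also lower. Fat cell genes had 3 higher and 3 lower of 9 (adjusted p = 0.71), with Cidea, a lipid droplet protein, at least 17.6-fold higher, Cidec and Fabp4 higher, Car3 at -4.72, and Cfd and Plin4 lower. Pancreatic acinar genes had 1 higher and 3 lower of 7 (adjusted p = 0.13, but 0.0055 by fry and 0.03 with the classes normalized separately), with Cela1 3.49-fold higher, Cela2a at least 15.2-fold lower and Ctrb1 and Amy2a5 also lower. Erythroid genes had 1 higher and 3 lower of 9 (adjusted p = 0.4), with the haem enzymes Fech and Alas2 at -1.43 and -0.89, Klf1 also lower and Bpgm higher. Calls were lost for Clec4g in 6 of 19, Cidec in 5 of 18 and Bpgm in 6 of 19 alternatives, with adjusted p up to 0.65, 0.095 and 0.089. The medians of the acinar and erythroid lists, -0.20 and -0.17, became 0.03 and 0.06 with spike-in scaling. Adjusted over the list alone, 14 cholangiocyte, 6 mesothelial and 4 fat cell genes were higher, and the other counts were unchanged.

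Genes of hepatocyte functions were lower in most of the lists, as measured in RNA of whole liver. Whether a lower share of hepatocyte RNA contributed to these falls, or to those of energy and secretion genes below, was not tested. Urea cycle and amino acid genes fell in 41 of 46 cases and none rose, median -1.44 (adjusted p = 1.2e-18; adjusted p = 0.22 with an estimated correlation). Glutamine synthetase, Glul, fell by 3.50 log2 and the methyltransferase Bhmt fell by 3.25 from a vehicle mean of 17.93, also near the top of the intensity range. Of 48 cytochrome P450 genes, 33 fell, median -1.34 (adjusted p = 4.8e-12; adjusted p = 0.19 with an estimated correlation). Cyp2c38 and Cyp2c37 fell by 5.04 and 4.53, while Cyp3a44 was higher by 3.48, or by 2.65 (adjusted p = 0.072) without CCl4 replicate 1. Bile acid genes fell in 24 of 31 cases and rose in 3, median -1.24 (adjusted p = 1.6e-08; adjusted p = 0.19 with an estimated correlation). The uptake transporter Slco1a1 fell by 6.07, and the risers were the export pumps Abcb1a (1.91) and Abcc4 (1.46) and the receptor Fgfr4 (0.71). Pericentral genes fell in 21 of 31 cases, median -1.38 (adjusted p = 6e-08; adjusted p = 0.26 with an estimated correlation), and periportal genes in 18 of 27, median -1.16 (adjusted p = 1e-04; adjusted p = 0.19 with an estimated correlation). Slc1a2 and Cyp2c37 fell most among pericentral genes and Etnppl (-3.57) and G6pc (-2.78) among periportal ones, against rises of Lect2 (1.39) and Gstm2 in the first and of Apoa4 (1.87), Ctsc, Cdh1 and Aldh1b1 in the second. Gstm2 lost its call in 15 of 19 alternatives, with adjusted p up to 0.2. Both zone lists share many members with other lists, such as Glul and Cyp2c37 (pericentral) and G6pc and Igfals (periportal). Their falls are therefore not separate from those of the other lists. Adjusted over the list alone, 35 P450 genes were lower, and 4 bile acid genes, 5 periportal genes and 1 amino acid gene were higher.

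Genes of energy metabolism and secretion fell as well, and those of cholesterol synthesis rose. Fatty acid oxidation and PPAR-alpha target genes fell in 23 of 40 cases and rose in 4, median -0.70 (adjusted p = 3.1e-06; adjusted p = 0.26 with an estimated correlation). The peroxisomal thiolase Acaa1b fell by 2.33, while the hormone Fgf21 rose by 3.41, with Acot2, Pdk4 and Bdh1 also higher. Gluconeogenesis and glycogen genes fell in 14 of 21 cases and rose in 2, median -0.81 (adjusted p = 2.8e-05; adjusted p = 0.24 with an estimated correlation), with glycogen synthase Gys2 at -2.25, Pgm2 at 2.10 and Igfbp1 also higher. Calls were lost for Acot2 in 3 of 18, Igfbp1 in 2 of 19 and Foxa3 in 4 of 19 alternatives, with adjusted p up to 0.095, 0.058 and 0.081. Secreted proteins and liver transcription factors fell in 31 of 50 cases and rose in 4, median -0.50 (adjusted p = 1.6e-06; adjusted p = 0.19 with an estimated correlation). The IGF carrier Igfals fell by 2.65 and the factor Onecut1 was 4-fold lower, while the clotting factor F11 rose by 1.18, with Foxa3, Apoc2 and Kng1 also higher. With spike-in scaling only 15 genes of that list and 15 of the fatty acid oxidation list were lower. Glutathione, NRF2 target and conjugation genes fell in 23 of 45 cases and rose in 10, median -0.42 (adjusted p = 0.0011; adjusted p = 0.27 with an estimated correlation). The glucuronosyltransferase Ugt2b1 fell by 3.30, while Akr1b7 and G6pdx, both enzymes of redox metabolism, rose by 3.64 and 2.27. Cholesterol synthesis went the other way, with 20 of 25 genes higher and 1 lower, median 1.90 (adjusted p = 2.4e-10; adjusted p = 0.26 with an estimated correlation). Squalene epoxidase, Sqle, rose by 4.87 and Mvd by 3.50, and Acat2 had -0.64, or -0.41 (adjusted p = 0.098) with spike-in scaling. Lipid synthesis genes split evenly, 10 higher and 10 lower of 29 (adjusted p = 0.99), with a median of -0.14, a mean of 0.02 and a spike-in scaled median of 0.09. Pnpla3 rose by 3.53 and Mlxipl, a glucose-sensing factor, fell by 1.93. Adjusted over the list alone, 26 fatty acid oxidation, 17 gluconeogenesis, 34 secretion and 25 glutathione genes were lower, and 21 cholesterol genes were higher and 2 lower.

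Stress, division and inflammation genes of the liver rose. ER stress and integrated stress response genes rose in 23 of 31 cases and fell in 1, median 1.28 (adjusted p = 2.6e-11; adjusted p = 0.16 with an estimated correlation), with the factor Atf3 at 5.26, the serine enzyme Psat1 at 6.11 by its brightest probe and 2.14 by its other bright one, and Ern1 lower. Cell cycle genes rose in 29 of 35 cases, median 1.81 (adjusted p = 4e-13; adjusted p = 0.24 with an estimated correlation), led by Ccnd1 (4.29). The falling member, Tyms, had -0.86, with an adjusted p of 0.0377 that became 0.11 without CCl4 replicate 2. The p53 target and senescence genes rose in 17 of 24 cases and fell in 2, median 1.29 (adjusted p = 5e-06; adjusted p = 0.24 with an estimated correlation). The death receptor Tnfrsf10b rose by 4.12 and Phlda3 by 3.93, and Plk3 fell by 1.92, with Ei24 also lower. Fetal liver and progenitor genes rose in 13 of 19 cases, median 2.75 (adjusted p = 8.3e-06; adjusted p = 0.23 with an estimated correlation), led by Ly6d, while Peg3 had -1.08, with an adjusted p of 0.071 without CCl4 replicate 1. Acute phase genes rose in 21 of 31 cases and fell in 2, median 1.31 (adjusted p = 1.2e-07; adjusted p = 0.26 with an estimated correlation), with the iron-binding Lcn2 at 6.14, to a CCl4 mean of 17.71 near the top of the range, and Orm3 at 4.48. The fall of Saa4 (-0.69) had an adjusted p of 0.19 without CCl4 replicate 1, and that of Crp (-0.52) one of 0.28 with spike-in scaling. Interferon response genes rose in 27 of 39 cases, median 0.81 (adjusted p = 2.8e-09; adjusted p = 0.26 with an estimated correlation), led by Ifi27l2a (2.90) and Oas1a (2.88), with Cxcl9 lower. Immediate early and RNA handling genes rose in 14 of 27 cases, median 1.28 (adjusted p = 1.7e-05, or 0.26 with an estimated correlation), with Egr2 at 4.68 and Dusp1 lower. Whether a difference in tissue handling between the groups contributed to that rise was not tested. Calls were lost for Ern1 in 6 of 19, Ei24 in 1 of 19, Cxcl9 in 4 of 19 and Dusp1 in 13 of 19 alternatives, with adjusted p up to 0.36, 0.067, 0.09 and 0.19. Adjusted over the list alone, 23 acute phase, 29 interferon and 16 immediate early and RNA handling genes were higher, and the other counts were unchanged.

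Genes with higher expression in male than female liver fell in 20 of 25 cases and none rose, median -1.75 (adjusted p = 5.5e-10; adjusted p = 0.26 with an estimated correlation). Hsd3b5 and Elovl3 fell most. Female-biased genes rose in 12 of 26 cases and fell in 2, median 0.84 (adjusted p = 0.00098; adjusted p = 0.24 with an estimated correlation). The largest risers, Prom1 and the macrophage and osteoclast proton pump subunit Atp6v0d2 (4.81), are also expressed outside hepatocytes. Among the P450s of that list, Cyp3a44 rose, while Cyp2g1 and Cyp3a16 fell by 2.58 and 2.09. The clock list, with 3 higher and 8 lower of 22, was not called (median -0.26, adjusted p = 0.11), though 6 of 22 alternatives called it lower. Over all 22 alternatives its adjusted p ranged from 0.016 to 0.37. Nr1d1 and Dbp, which oscillate daily in liver, fell by 2.17 and 2.02, and Wee1 rose by 1.29, with Noct and Tspan4 also higher. The mean of its probes gave 0.03 for Noct (adjusted p = 0.91), and Wee1 had an adjusted p of 0.052 with the replicate number as a block. With p adjusted over the list alone, 22 male-biased and 10 clock genes were lower.

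Which long non-coding RNAs differ was the next question. After CCl4 more of them were lower than higher on the deposited scale, where more protein-coding genes were higher. The transcripts with the largest changes lay mostly within genes that changed the same way. A RIKEN clone inside Col1a1, ri|I420015C23, rose 118-fold, from 6.16 ± 0.27 (SD, n = 3) to 13.04 ± 0.20 (SD, n = 2). A clone inside Slc1a2, ri|6330527N22, was 292-fold lower, at 5.35 ± 0.25 (SD, n = 2) against 13.54 ± 0.27 (SD, n = 3). These clones ended at 94953040 and 102790779, where Col1a1 and Slc1a2 end at 94953042 and 102790784. Likewise, uc011zab.2 and uc012ezu.1, described below, start where Cxcl14 and Sult2a8 start. Probes of such transcripts can have read the messenger RNA, so their changes may not be those of separate non-coding RNAs.

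Of 27370 non-coding transcripts tested, 7815 (28.6%) passed, 2996 higher and 4819 lower, with 1302 and 1816 of these changed at least 2-fold. The median change was -0.129 log2, against 0.088 for protein-coding genes, and both CCl4 arrays lay on the same side of all vehicle arrays in 57.5%, where chance gives 20%. Lower transcripts outnumbered higher ones among 18343 FANTOM clones (1876 higher, 3090 lower), 3386 Agilent lincRNAs (273 and 644), 433 ultraconserved regions (17 and 70) and 566 Ensembl transcripts (51 and 110). The same held for 957 RefSeq transcripts (150 and 184) and 561 non-coding genes on the ordinary gene panel (59 and 115), while 3104 UCSC transcripts split into 566 and 598 and 20 lncRNAdb entries into 3 and 3. That balance moved with the scaling: spike-in scaling gave 4088 higher and 2058 lower, and cyclic loess 3374 and 4164. Separate normalization of the classes gave 3804 and 3698, an even split that it sets by construction. Leaving out single arrays mattered as well, with 2699 lower and 1893 higher without vehicle replicate 1, 2705 and 1932 without vehicle replicate 2, and 3113 lower without CCl4 replicate 1.

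On GRCm38, ri|I420015C23 lay on chromosome 11 at 94951640 to 94953040, within Col1a1, and its 3 bright probes ranged from 2.29 to 6.88. The transcript uc007pgn.1 rose by 6.57 and lay on chromosome 12 at 113302967 to 113306834, overlapping in part the immunoglobulin constant region gene Ighg2b. The transcript uc011zab.2 rose by 6.43 on chromosome 13 at 56288643 to 56296551, the position of Cxcl14, which rose by 6.25. The clone ri|3526401J04 was at least 40.8-fold higher and lay on chromosome 13 at 58934122 to 58937024, within the neurotrophin receptor gene Ntrk2 (3.22), though its other bright probe gave 0.25. A clone the files identify by PX00105N24, at least 27.6-fold higher, had no location in the annotation. Among the falls, ri|6330527N22 (-8.19) lay on chromosome 2 at 102787622 to 102790779, within Slc1a2, with probes from -8.19 to -3.38. The transcript uc012ezu.1 (-6.67 log2) lay on chromosome 7 at 14410686 to 14446587, the position of Sult2a8, and ri|C230009C09 (-6.27, with probes from -6.45 to -2.10) on chromosome 1 at 182892230 to 182896580, within Susd4. The clones ri|2010200M04, at least 111-fold lower, and ri|9630038B04, at least 21.9-fold lower but with another bright probe at -0.62 log2, had no location.

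Among 7025 located non-coding transcripts that overlapped exactly 1 tested protein-coding gene, their change correlated across genes with that of the overlapped gene (Pearson's r = 0.49, Spearman's rho = 0.46, permutation p = 1e-04, the smallest that 10000 permutations can give). This was the one such relation computed, two-sided, and genes are not independent replicates. Where both passed the test, 1311 of 1518 (86.4%) moved in the same direction, against 50.6% by chance. The reference gives no strand or exons, so a probe there can also have read the messenger RNA. Transcripts overlapping no tested protein-coding gene numbered 3485, of which 351 were higher and 597 lower (median -0.12), against 1209 and 1393 of the 7623 that overlapped any (median -0.08).

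**Figure D3:**
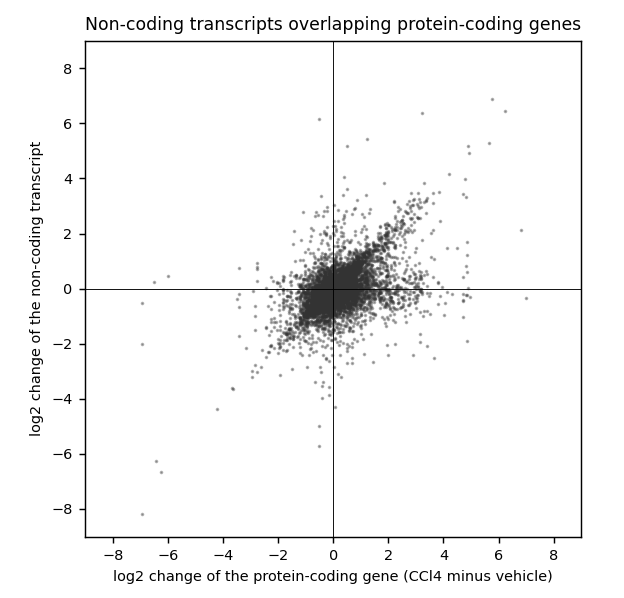
Log2 change (CCl4 minus vehicle) of each of 7025 non-coding transcripts (vertical axis) against that of the 1 protein-coding gene it overlapped (horizontal axis), with 1 point per transcript. The points followed the diagonal in part (Pearson's r = 0.49), with a band near 0 on the vertical axis at genes that rose.

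Of 47 long non-coding RNAs with a gene symbol, 12 rose and 4 fell (median 0.19, adjusted p = 0.12, or 0.0042 by fry; 12 and 4 also adjusted over the list alone). The small nucleolar RNA host genes Snhg18 (2.80) and Snhg1 (1.92) rose, while C730036E19Rik was at least 9.5-fold lower, with Snhg11, Dleu2 and Mir22hg also lower. The brightest Snhg11 probe, at -4.00 log2, was detected on 1 of 2 CCl4 arrays, and its other bright probe gave -0.96. H19 had a log2 change of 0.37 (adjusted p = 0.577) and Meg3 of 0.05 (0.73), both imprinted RNAs. Malat1 had 0.22 (adjusted p = 0.412), but the mean of its probes gave 0.99 (adjusted p = 0.0065). Gas5, a growth arrest transcript, had 0.46 (adjusted p = 0.0477), a call lost in 9 of 19 alternatives, among them those without CCl4 replicate 1 (0.27, adjusted p = 0.22), vehicle replicate 1 (0.43, 0.14), vehicle replicate 2 (0.43, 0.13) or vehicle replicate 3 (0.52, 0.057).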

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

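Alternatives numbered 24, of which spike-in scaling, separate normalization of the classes, the filter on flags and the protein-coding background were chosen after seeing the data. Counts stayed within 1.5 times the reported one in 141 cases and moved further in 29. Stricter calls lowered the counts by construction: at least 2-fold left 3207 protein-coding genes (2224 higher, 983 lower) and 3118 non-coding transcripts (1302 and 1816), and an adjusted p of 0.01 left 4268 (2810 and 1458) and 3338 (1437 and 1901). Fewer non-coding transcripts were tested with a filter at the 75th percentile (5095 changed, 1728 higher) and with the mean of the probes (4763 changed, 1867 higher, 2896 lower). Spike-in scaling gave 1298 protein-coding genes and 2058 non-coding transcripts lower, since it shifts every gene up. Over the fits without 1 array, protein-coding genes lower ranged from 1740 (without vehicle replicate 1) to 2387, non-coding transcripts changed from 4592 (without vehicle replicate 1; 4637 without vehicle replicate 2) to 7284, higher from 1893 (1932 without vehicle replicate 2) to 2611, and lower from 2699 (2705 without vehicle replicate 2, 3113 without CCl4 replicate 1) to 4815. These fits have fewer arrays, and without a CCl4 array the remaining one is assumed to vary like the vehicle arrays. With the replicate number as a block, 6035 protein-coding genes (3802 and 2233) and 6747 non-coding transcripts (2354 and 4393) passed, and the lists gave 19 higher and 10 lower; whether the numbers pair the arrays is not known, and 2 CCl4 arrays are too few to tell. Camera with an estimated correlation called 0 lists higher and 0 lower. Among single lists, 786 results kept their side of the threshold, 34 were weaker and 13 stronger. Direction was compared only where a result passed, so an uncalled result that changed direction counts as kept. Among 155 named genes, by the same rule, 2750 results kept their side, 140 were weaker, 3 stronger and 1 reversed. The reversed one was Vcan, for which the mean of its 3 probes gave 2.77. Only 1 of these passed the brightness filter, at -0.42, so the rise came from the dimmer ones. Why the probes differed was not tested. Repeated quantile normalization and median centring moved next to nothing, since the values were already equalised, and say nothing about stability. Signal over background limits dim genes, whose folds are lower bounds where a group was not detected.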

Other observations

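All tests below except the brightness matching were chosen only after the result was seen, and the same holds for 16 gene families grouped by symbol. Ribosomal protein genes (Rpl, Rps) rose in 64 of 78 cases and fell in 1, median 0.44 log2, and aminoacyl-tRNA synthetase genes, which charge transfer RNAs, rose in 12 of 17, median 0.63. Annexins, which bind membranes with calcium, rose in 8 of 11 cases, led by Anxa2 (4.85), and Ms4a genes of blood cells in 10 of 14, led by Ms4a3 (at least 24.2-fold). S100 genes rose in 8 of 12 cases and fell in 2, led by S100a8 (6.64). Genes with tubulin symbols (Tub) rose in 9 of 21, V-ATPase genes in 9 of 21, cathepsins in 7 of 14 and keratins in 7 of 26 cases. Those lower numbered 1, 1, 3 and 1. Among all protein-coding genes 4300 of 14937 were higher, so keratins rose no more often than genes at large. The keratin median of 0.30 became 0.08 with the classes normalized separately. Carboxylesterases fell in 12 of 14 cases, median -1.55, and the pheromone-binding major urinary proteins in 5 of 11, median -1.46, with Mup6 lowest (-3.57). Genes of mitochondrial complex I (Nduf) fell in 25 of 47 cases and none rose, median -0.41, but with spike-in scaling 5 were lower and the median was -0.17. Peroxisome biogenesis genes (Pex) fell in 9 of 17 cases and Slc22 transporters in 7 of 15, and with spike-in scaling in 7 and 6. Genes with proteasome symbols (Psm, 3 higher and 2 lower of 38) and histone genes (12 and 14 of 59) went both ways. Their medians of -0.08 and -0.06 became 0.16 and 0.18 with spike-in scaling. The highest of the Psm set, Psmc3ip (1.47), is not a proteasome subunit. The medians of the other families kept their sign under cyclic loess, spike-in scaling and separate normalization of the classes.

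Where called genes had several bright probes, the probes differed in sign for 271 of 2093 protein-coding genes and 1301 of 4853 non-coding transcripts, by over 2-fold both ways in 12 and 45.

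Non-coding RNAs were more often lower and protein-coding genes more often higher. A different brightness of the classes was argued against, since the gap of 0.22 log2 between the class medians was 0.27 after matching by brightness. The probe design of the non-coding part of the array was argued against as well, because non-coding genes on the ordinary gene panel lay at -0.23 log2 relative to protein-coding genes there (permutation p = 1e-04, the smallest possible). Genes were permuted here, so that p does not measure spread between arrays. A zero point set by the normalization of the arrays stays open for the direction of the non-coding RNAs: spike-in probes were lower on the CCl4 arrays by more than the median non-coding fall in 4 of 6 array pairs, and with their scaling 66.5% of non-coding calls were higher, not 38.3%. A difference in RNA composition after CCl4 was not tested on its own, so the fall of the non-coding RNAs may be relative to the array-wide scale alone.

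Male-biased liver genes were lower. CCl4 arrays from female livers are argued against by a median change of -0.31 log2 over the Y-linked genes Ddx3y, Eif2s3y and Uty, of which Uty was lower (-0.67, adjusted p = 0.0245), and by Xist, which no array detected. A lower share of hepatocyte RNA as the whole cause is argued against by a difference of -1.43 log2 between the medians of 20 male-biased and 220 other hepatocyte genes (-2.41 and -0.97, permutation p = 2e-04), both limited to vehicle means up to 17 log2. That p comes from permuting genes, which are not independent replicates, and does not measure spread between arrays. The correlation estimated within the male-biased list was 0.56. A shift of hepatocytes to the female pattern cannot be told apart from loss of the male pattern alone, since 3 of 14 female-biased enzyme and Cux2 genes rose and 2 fell. A direct effect of CCl4 on male-biased genes stays open as well and was not tested.

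Cholesterol synthesis genes were higher. Another time of day at harvest cannot be told apart from an effect of CCl4, because Nr1d1, Dbp, Tef and Nr1d2 fell, with a median change of -1.99 log2, while Arntl, Clock and Cry1, which peak at opposite times, had a median of 0.31 and none passed the test; Npas2 was too dim to be tested, and the criterion was set after these values were seen. The labels give no harvest times or feeding states, so a direct effect of CCl4 may be part of the rise but was not separated from them.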
